A study of Mus musculus with 36 samples.

How the data were processed

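Total RNA of whole kidneys from C57BL/6 mice of 4 genotypes (wild type, Pkd1-RC/RC, Pkhd1-/- and digenic) at postnatal days 0, 3 and 12 was sequenced as 150 bp paired-end reads on a HiSeq4000, with 3 libraries per group and 36 in all. Groups were taken from the sample labels. In 2 libraries the column headers differ from the labels: digenic replicate 1 of P12 has a header with P3, and Pkd1-RC/RC replicate 2 of P12 has a header with Pkhd1; the labels were used, and the Pkhd1 level of the latter library lay with those of unmutated kidneys. Strandedness of the libraries is not given in the sources used here.

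Reads were aligned to mm10 by the authors with TopHat2 and Bowtie through MAP-RSeq 2.1.0 and counted with featureCounts, per the submitters' processing notes, which also name edgeR. The deposited table holds, per the file headers, raw counts per gene and library, which were the input of every test here. The deposited normalized columns hold log2 values: RPKM plus 1 on the log2 scale, computed from the counts, matched 100% of values with at least 20 counts within a relative 0.001. This check used the normalized columns of 34 libraries, and the other 2 normalized columns were not used. The authors' deposited table also gives log2 fold changes with a p-value and FDR for each mutant against wild type of its age, which were compared with the fold change of the tests here but entered none of them. The authors' model is not given in the sources used here. The deposited table lists 18049 genes with a lowest mean of 8.75 counts, so that genes removed for low counts were not analysed here. The listed genes held 99.9% of the total that the normalized values rest on. Total counts per library ran from 51411240 to 80789299. Counting error is small at that depth for all but the lowest genes, and the spread between mice set the precision. Positions came from GENCODE M21 annotation, which held 17864 (99.0%) of the identifiers, 12551 (70.3%) of those with the same start and end as the deposited table.

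Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. For each age the 12 libraries were fitted together with a term per genotype, after filtering with filterByExpr (18035, 18043 and 18002 genes at P0, P3 and P12), scaling by TMM, dispersion estimation and a robust quasi-likelihood fit. Each mutant was compared with wild type, digenic with each single mutant, and the interaction was digenic minus Pkd1-RC/RC minus Pkhd1-/- plus wild type on the log2 scale. Changes of these effects from P0 to P12 and the wild-type change came from 1 fit of all 36 libraries (18049 genes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of its comparison. Log2 CPM levels of libraries used a prior count of 2, and fold changes came from the fit with edgeR's default. Genotype, age and their comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

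The rule named Pkd1, Pkhd1 and Pkd2 in every comparison. For each mutant against wild type and for the interaction it named the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 0, an official symbol and, except for the interaction, no overlap between the libraries of the groups, leaving out sex-linked genes. Hence each named rise or fall against wild type was seen in 3 of 3 mice, a separation that chance gives to 10% of genes. For digenic against a single mutant it named 4 rises and 4 falls, and for wild-type P12 against P0 5 of each with a mean log2 CPM of at least 3. For each list that passed it named up to 4 members with the smallest adjusted p in the direction of the list. Of the genes so named or listed, 2 are not reported here.

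Lists of genes, 35 in number with at least 5 measured members each where tested, covered nephron progenitor, ureteric tip, proximal tubule, loop of Henle, distal convoluted tubule, principal cell, intercalated cell, podocyte, endothelium, stroma, matrix and fibrosis, tubular injury, macrophage, neutrophil, lymphocyte, interferon response, cell cycle, glycolysis, fatty acid oxidation, oxidative phosphorylation, cilium, cystic disease genes, hedgehog, Wnt targets, YAP targets, cAMP and vasopressin, renin-angiotensin, unfolded protein response, immediate early, erythroid, adrenal, fat, muscle, gut, liver and pancreas, and sex-linked genes. Each was tested in each comparison with camera at a preset correlation of 0.01, adjusted over 412 tests. At that setting 141 tests passed and with an estimated correlation 0 did, with a smallest adjusted p of 0.205. The fry test, which asks whether the genes of a list move on balance 1 way, passed for 25 of the 412 tests. Members were also counted with p-values adjusted over the list alone.

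The position along the wild-type change was the weighted mean of log2 CPM over 3091 genes with at least a 2-fold wild-type change, scaled to 0 and 1 at the P0 and P12 wild-type means, and was compared by two-sided exact permutation. Correlations between mutant profiles were set against 20 simulations with shared controls. Closeness to the mutated gene was tested with Fisher's exact test over genes within 20 Mb. Tables used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.

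The procedure was tested on simulated data with 200 changed genes in place of the digenic comparison. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 7.46%, 67.2% and 97.0% at P0, 49.3%, 85.1% and 100% at P3 and 52.2%, 86.6% and 98.5% at P12, with 2.52%, 5.68% and 5.26% false calls. A comparison without changed genes called 0. Replicate numbers were checked for pairing between groups by correlating residuals: 2 of 18 pairs of groups had every correlation above 0.1 (P0 Pkd1-RC/RC with digenic, and P12 wild type with Pkhd1-/-), and a replicate block moved those counts from 7 to 6 and from 6 to 4. The numbers therefore pair nothing in general, and blocked values stand with the alternatives. No pair of libraries within a group was a duplicate among 36 pairs, with a lowest chi-square per gene of 18.0.

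Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, a replicate block, only the groups compared, all libraries in 1 fit, leaving out each library, camera with an estimated correlation, and other gene sets for overlaps and positions. Chosen after seeing the data were sex as a term (from the Xist and Ddx3y pattern or from the column headers), leaving out the 8 libraries with Cyp11a1 above 10 CPM, leaving out genes within 20 Mb of the mutated genes, removing the gene length trend of each library (lowess span 0.3), leaving out libraries for positions and overlaps, and, in the test of closeness, counting overlapping genes once and leaving out each library.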

Results

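RNA from whole kidneys of C57BL/6 mice was sequenced at postnatal days 0, 3 and 12 (P0, P3 and P12) in 4 genotypes. These were wild type, Pkd1-RC/RC, Pkhd1-/- and digenic mice with both mutations. Pkd1 encodes polycystin-1, the main gene of dominant polycystic kidney disease, and RC is a point allele with reduced function. Pkhd1 encodes fibrocystin, the gene of recessive polycystic kidney disease. Each group of age and genotype held 3 libraries with 1 library per mouse, so that p-values measure the spread between mice, and there were 36 libraries in all. Total counts over the 18049 listed genes ran from 51411240 to 76481287 per library at P0, from 52278185 to 78461405 at P3 and from 53152909 to 80789299 at P12. Levels below are CPM as mean ± SD over n = 3 mice. For Pkhd1, Pkd1 and Pkd2 these are read counts scaled by library total. For the other genes the library total was first multiplied by its TMM factor, from the 12 libraries of an age or, for wild-type P12 against P0, from all 36. Changes are log2 fold changes ± SE from the fit of the 12 libraries of an age. For lists of genes the first adjusted p rests on a preset correlation between genes and the second on an estimated one, with which no list passed.

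Pkhd1 (ENSMUSG00000043760, chromosome 1: 20057779 to 20618064, mm10) was lower in every library carrying its mutation. In wild-type kidneys it stood at 70.01 ± 6.61 CPM at P0, 90.6 ± 23.4 at P3 and 215 ± 42.9 at P12 (n = 3 each). Pkhd1-/- kidneys held 7.05 ± 1.74, 7.75 ± 1.65 and 19.6 ± 0.527 CPM at these ages, and digenic kidneys 9.84 ± 0.928, 11.54 ± 0.754 and 23.2 ± 6.98 CPM. The change in Pkhd1-/- was -3.29 ± 0.234 at P0, -3.50 ± 0.206 at P3 and -3.46 ± 0.191 at P12, with adjusted p-values of 5.12e-05, 5.83e-06 and 7.32e-06. In digenic kidneys it was -2.86 ± 0.229, -2.98 ± 0.200 and -3.18 ± 0.189, with adjusted p-values of 0.000213, 1.45e-05 and 5.75e-06. In Pkd1-RC/RC kidneys Pkhd1 stood at 86.1 ± 21.1, 103.02 ± 18.9 and 228 ± 4.96 CPM. Pkd1 (ENSMUSG00000032855, chromosome 17: 24549950 to 24596514) carries a point mutation, so its level checks nothing about the genotype. It stood at 52.8, 70.8 and 87.2 CPM in wild type and at 59.5, 67.0 and 89.8 CPM in Pkd1-RC/RC at P0, P3 and P12. Pkd1 passed the test in no comparison of genotypes at 1 age. Pkd2 (ENSMUSG00000034462, chromosome 5: 104459450 to 104505819), which encodes polycystin-2, the channel partner of polycystin-1, was 0.26 ± 0.0783 lower on the log2 scale in digenic than in Pkd1-RC/RC kidneys at P12 (adjusted p = 0.0334). Digenic kidneys held 189 CPM, near the wild-type 176, and Pkd1-RC/RC kidneys 238 CPM. That call was lost without Pkd1-RC/RC replicate 2 or 3 or digenic replicate 1 or 2, where the change was -0.27, -0.20, -0.26 and -0.21.

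**Figure D1:**
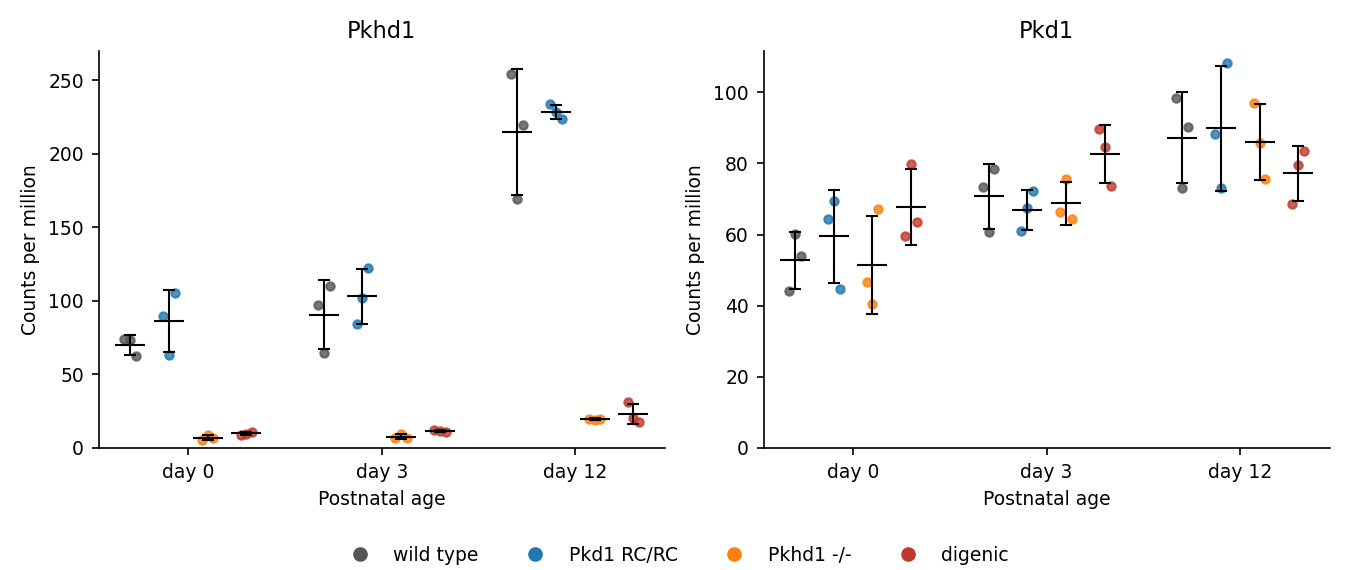
CPM of Pkhd1 and Pkd1 in each library (points) by postnatal day and genotype, with bars for the mean and SD of 3 mice. Pkhd1-/- and digenic libraries lie far below the wild-type means of 70.01, 90.6 and 215 CPM for Pkhd1, while the genotypes overlap for Pkd1.

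At P0, few genes separated a single mutant from wild type in the fit of that age, while the fit of all 36 libraries called 353 in Pkd1-RC/RC and 18 in Pkhd1-/-. In Pkd1-RC/RC kidneys 3 of 18035 tested genes rose and 0 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1880 genes at an unadjusted p under 0.05 and 113 called by DESeq2. The 3 genes, chosen after their values were seen, were the processed pseudogenes Gm13443 (1.90 ± 0.253), Gm14292 (1.66 ± 0.216) and Gm9825 (1.49 ± 0.169), which may share reads with other copies and so are uncertain. In Pkhd1-/- kidneys Pkhd1 and the transcript 4930486I03Rik (-6.00 ± 0.746), antisense to it and counted from overlapping sequence, fell and 0 genes rose, with 849 at an unadjusted p under 0.05 and 9 by DESeq2. Of the lists, cell cycle genes rose in Pkd1-RC/RC (25 members, median 0.34, adjusted p = 7.49e-07), with 0 members past the test over all genes and 4 up adjusted over the list alone. That list had adjusted p = 0.540 with an estimated correlation. At P0 log2 levels correlated with gene length across genes by -0.193 to -0.0378 in wild-type and by 0.0667 to 0.160 in Pkd1-RC/RC libraries, and with that trend removed the cell cycle median was 0.29. YAP target genes fell in Pkhd1-/- (12 members, median -0.31, adjusted p = 6.35e-05; adjusted p = 0.430). Member calls were 0 over all genes and 2 down adjusted over the list alone. The cell cycle median was 0.13 without wild-type replicate 2, and the YAP target median was -0.19 without wild-type replicate 1. The count of 3 became 0 without wild-type replicate 1, 2 or 3 and 1 without Pkd1-RC/RC replicate 1, and the count of 2 became 1 without any 1 wild-type replicate or Pkhd1-/- replicate 3.

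Digenic kidneys at P0 differed from wild type at 121 genes. Miox, the inositol-catabolic enzyme of the proximal tubule, fell from 153 ± 48.9 to 9.91 ± 0.440 CPM (-3.94 ± 0.432, adjusted p = 0.00197), and Haao, an enzyme of tryptophan catabolism, fell from 13.6 ± 3.99 to 0.590 ± 0.111 CPM (-4.53 ± 0.494, adjusted p = 0.00197). Prodh2, which catabolises hydroxyproline, fell by 2.68 ± 0.374 (adjusted p = 0.00761). Ankrd1, a target of the YAP coactivator, rose from 1.41 ± 0.181 to 7.35 ± 0.827 CPM (2.37 ± 0.225, adjusted p = 0.000823). Gdf15, a secreted stress factor, rose from 4.63 ± 0.368 to 26.6 ± 3.28 CPM (2.52 ± 0.326, adjusted p = 0.00417). Havcr1, the kidney injury marker KIM-1, rose from 0.604 ± 0.352 to 8.41 ± 5.19 CPM (3.78 ± 0.547, adjusted p = 0.00896), a call lost without wild-type replicate 1 or 3 (3.57 and 3.52). Bst1, an NAD-metabolising surface enzyme, rose by 2.29 ± 0.291 (adjusted p = 0.00400), and Folh1, a folate hydrolase, by 3.43 ± 0.489 (adjusted p = 0.00830; 3.14 and not called without wild-type replicate 3). The rule for named genes also gave Kmo (2.79 ± 0.565), B4galnt2 (2.31 ± 0.425) and Cyp4a12b (2.25 ± 0.421, uncertain through its close paralogs) among the rises. Among the falls it gave Kap (-3.60 ± 0.542), Crisp1 (-3.42 ± 0.639, within 20 Mb of Pkd1), Slc22a7 (-2.81 ± 0.513) and Crabp1 (-2.32 ± 0.473). These 7 genes lost the call when at least 4 of the 6 libraries were left out in turn.

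In all, 121 of 18035 genes passed at P0 in digenic kidneys (84 up, 37 down), 83 of them by at least 2-fold, with 704 by DESeq2 and 1645 in the fit of all 36 libraries. The count was 26 without wild-type replicate 1, 21 without wild-type replicate 3, and 37, 31 and 56 without digenic replicate 1, 2 and 3. Proximal tubule genes fell (30 members, median -0.43, adjusted p = 4.77e-07; adjusted p = 0.653). Called members were 2 down over all genes, and 1 up and 12 down adjusted over the list alone, with a median of -0.28 without wild-type replicate 2. Intercalated cell genes fell (14 members, median -0.72, adjusted p = 5.61e-07; adjusted p = 0.280). Member calls were 1 down over all genes, and 1 up and 9 down adjusted over the list alone. Foxi1, the transcription factor of intercalated cells, was the member called over all genes (-1.19 ± 0.206, adjusted p = 0.0242). Tubular injury genes rose (25 members, median 0.39, adjusted p = 0.000193; adjusted p = 0.540). Called members were 2 up over all genes, and 4 up and 1 down adjusted over the list alone. YAP targets rose (12 members, median 0.45, adjusted p = 9.19e-08; adjusted p = 0.280). Member calls were 2 up over all genes and 6 up adjusted over the list alone, among them F3, which encodes tissue factor (0.86 ± 0.157, adjusted p = 0.0304). Foxi1 and F3 each lost the call without 5 of the 6 libraries in turn. Interferon response genes fell (17 members, median -0.95, adjusted p = 1.06e-06; adjusted p = 0.586). Called members were 0 over all genes and 8 down adjusted over the list alone. Transcripts of other tissues differed as well: the gut, liver and pancreas list fell (median -0.55, adjusted p = 0.000820; adjusted p = 0.360; median -0.36 without wild-type replicate 2), with 0 members called over all genes and 3 down adjusted over the list alone. Muscle genes missed the threshold (median -0.44, adjusted p = 0.0547).

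Ankrd1 and Gdf15 were also higher in digenic kidneys than in either single mutant at P0. Against Pkd1-RC/RC, 7 genes passed (5 up, 2 down; 64 by DESeq2), including Ankrd1 (2.49 ± 0.226, adjusted p = 0.000493), Gdf15 (2.34 ± 0.323, adjusted p = 0.0186), Bst1 (2.12 ± 0.289, adjusted p = 0.0186) and Selenbp2, a selenium-binding protein (1.18 ± 0.174, adjusted p = 0.0336). The latter 3 genes lost the call without at least 4 of the 6 libraries in turn, and the count was 3 without Pkd1-RC/RC replicate 1 and 2 without digenic replicate 2. Against Pkhd1-/-, 44 genes passed (31 up, 13 down; 502 by DESeq2), including Ankrd1 (3.20 ± 0.235, adjusted p = 7.66e-05), Gdf15 (3.20 ± 0.336, adjusted p = 0.00179) and Haao (-3.70 ± 0.480, adjusted p = 0.00658). That count was 29, 20 and 306 without Pkhd1-/- replicate 1, 2 and 3, and 28, 19 and 23 without digenic replicate 1, 2 and 3. The interaction asks whether the digenic change differs from the sum of both single changes, and Ankrd1 was the 1 gene that passed it (3.31 ± 0.318, adjusted p = 0.00188; 8 genes by DESeq2, and 3 without Pkd1-RC/RC replicate 3). YAP targets rose in the interaction as a list (median 0.88, adjusted p = 2.60e-20; adjusted p = 0.205). Member calls were 1 up over all genes and 8 up adjusted over the list alone. Tubular injury genes did too (median 0.45, adjusted p = 1.64e-09; adjusted p = 0.280). Called members were 0 over all genes, and 7 up and 1 down adjusted over the list alone, with a median of 0.28 without wild-type replicate 2.

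At P3, the single mutants again differed little from wild type. In Pkd1-RC/RC kidneys Grm4, a glutamate receptor gene (2.62 ± 0.327, adjusted p = 0.00791), rose, and Rsph3a, a radial spoke gene of motile cilia (-1.09 ± 0.111, adjusted p = 0.00219), Decr2, a peroxisomal reductase gene (-0.88 ± 0.135, adjusted p = 0.0455), and Rnps1, an RNA-binding protein gene (-0.70 ± 0.0958, adjusted p = 0.0166), fell; these 4 lie within 20 Mb of Pkd1 on chromosome 17. The other 4 called genes, chosen after their values were seen, rose and lie on chromosomes 2 and 6. They were the processed pseudogenes Gm13443 (1.735 ± 0.212), Gm14292 (1.675 ± 0.180), Gm9825 (1.85 ± 0.112, adjusted p = 8.275e-06) and Gm15487 (1.325 ± 0.156), uncertain since they may share reads with other copies. Gm13443 and Gm15487 lost the call without wild-type replicate 1 (1.66 and 1.26). Grm4, Decr2 and Rnps1 lost the call without 2, 5 and 4 of the 6 libraries in turn. In Pkhd1-/- kidneys Snhg6, a noncoding RNA gene on chromosome 1 (9941959 to 9944118), fell from 20.5 to 6.68 CPM (-1.62 ± 0.152, adjusted p = 0.000833), beside Pkhd1 and its antisense transcript. The counts were 8 genes in Pkd1-RC/RC (5 up, 3 down; 65 by DESeq2) and 3 in Pkhd1-/- (0 up, 3 down; 396 at an unadjusted p under 0.05; 12 by DESeq2). The count of 8 was 3 without wild-type replicate 1 and 13 without wild-type replicate 3, and both counts were 1 without the libraries that held adrenal transcripts. Glycolysis genes rose in Pkd1-RC/RC (17 members, median 0.27, adjusted p = 7.05e-14; adjusted p = 0.342). Member calls were 0 over all genes and 5 up adjusted over the list alone, with a median of 0.41 without wild-type replicate 2. Podocyte genes fell there (15 members, median -0.20, adjusted p = 7.05e-07; adjusted p = 0.265). Called members were 0 over all genes or adjusted over the list alone. Nephron progenitor genes fell in Pkhd1-/- (median -0.19, adjusted p = 1.68e-05; adjusted p = 0.430). Member calls were 0 over all genes or adjusted over the list alone. The median was -0.16 and not called without wild-type replicate 2, and -0.28 without wild-type replicate 3.

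In digenic kidneys at P3, genes that answer interferon rose together. Of the 17 measured members of the interferon response list 14 rose over all genes and 17 adjusted over the list alone, with a median of 1.64 (adjusted p = 9.25e-33; adjusted p = 0.268). Ifit1, which binds viral RNA, rose from 2.87 ± 0.708 to 17.2 ± 11.1 CPM (2.58 ± 0.369, adjusted p = 0.00466), Oasl2 by 1.96 ± 0.287 (adjusted p = 0.00548) and Isg15, a ubiquitin-like protein, by 1.96 ± 0.306 (adjusted p = 0.00705). The mean of the list stood 0.97 to 2.51 log2 units above wild type in the 3 digenic libraries. Macrophage genes rose (19 members, median 0.73, adjusted p = 3.52e-13; adjusted p = 0.280). Called members were 5 up over all genes and 15 up adjusted over the list alone. Among them Lyz2, lysozyme, rose by 1.37 ± 0.208 (adjusted p = 0.00569), Cd163, a scavenger receptor, by 1.26 ± 0.211 (adjusted p = 0.00849) and Csf1r, the receptor for macrophage growth factor, by 0.67 ± 0.120 (adjusted p = 0.0125). The named genes with the steepest rises were immunity genes, namely Tgtp1 (6.34 ± 1.31), Tgtp2 (6.13 ± 1.28), Gbp6 (5.68 ± 1.16), Serpina3f (5.05 ± 0.984), Nlrc5 (5.003 ± 0.899), Ifi47 (4.34 ± 0.894) and Gbp5 (4.06 ± 0.883), and the overlapping gene Olfr56 (4.55 ± 0.874). Each of these 8 was called in 8 to 10 of its 16 alternatives and lost the call when any 1 wild-type replicate was left out; Tgtp1, Tgtp2, Olfr56, Ifi47 and Gbp6 overlap one another or have close paralogs and are uncertain. The 3 P3 digenic libraries were all from females, while wild type held 1 female and 2 males; the interferon list still rose with sex in the fit (adjusted p = 8.14e-27).

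Injury and signalling genes moved in the same P3 digenic kidneys. Tubular injury genes rose (25 members, median 0.37, adjusted p = 4.50e-07; adjusted p = 0.399). Member calls were 4 up over all genes and 7 up adjusted over the list alone, with a median of 0.24 without digenic replicate 2. Havcr1 rose by 3.83 ± 0.679 (adjusted p = 0.0159), a call lost without wild-type replicate 1 or 2 (3.98 and 3.41). YAP targets rose (median 0.41, adjusted p = 1.19e-05; adjusted p = 0.347; median 0.26 without wild-type replicate 2 and 0.250 without digenic replicate 2). Called members were 3 up over all genes and 4 up adjusted over the list alone, among them Ankrd1 (2.30 ± 0.388, adjusted p = 0.00902; 2.20 and not called without wild-type replicate 1). Hedgehog genes rose (10 members, median 0.27, adjusted p = 0.0360; adjusted p = 0.367). Member calls were 2 up over all genes and 3 up adjusted over the list alone, among them the ligand Ihh (1.11 ± 0.178, adjusted p = 0.00758) and its target Gli1 (0.83 ± 0.159, adjusted p = 0.0168). The hedgehog median was 0.18 and 0.15 and not called without wild-type replicate 1 and 3, and 0.17 without digenic replicate 2. Intercalated cell genes fell (14 members, median -0.32, adjusted p = 0.000207; adjusted p = 0.280). Called members were 3 down over all genes and 6 down adjusted over the list alone, such as the ammonia transporter Rhbg (-0.57 ± 0.114, adjusted p = 0.0203). Podocyte genes fell (15 members, median -0.28, adjusted p = 6.43e-05; adjusted p = 0.280). Member calls were 1 down over all genes and 6 down adjusted over the list alone. Csf1r, Rhbg and Gli1 lost the call without 2, 2 and 4 of the 6 libraries in turn. Of the other named falls, Sp110, a nuclear body gene, fell from 2.48 to 0.139 CPM (-4.15 ± 0.456, adjusted p = 0.000761), Cd8a, a T cell co-receptor, by 1.84 ± 0.263 (adjusted p = 0.00441) and Snhg6 by 1.60 ± 0.152 (adjusted p = 0.000329). Clec2h (-1.75 ± 0.378), Slc13a4 (-1.61 ± 0.368), Cyp4a14 (-1.53 ± 0.351) and Tph1 (-1.53 ± 0.348) were called in 8, 8, 5 and 6 of 16 alternatives.

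The P3 digenic comparison called 487 of 18043 genes (377 up, 110 down; 249 by at least 2-fold; 1118 by DESeq2). That count was 152 without wild-type replicate 1, 320 without wild-type replicate 3, and 245, 174 and 845 without digenic replicate 1, 2 and 3; with sex read from Xist and Ddx3y in the fit it was 54. Against Pkd1-RC/RC, 83 genes passed (59 up, 24 down; 525 by DESeq2), including Zbp1, a sensor of nucleic acids (4.54 ± 0.667, adjusted p = 0.0228), and Ccl12, a monocyte chemokine (2.65 ± 0.383, adjusted p = 0.0151), while Mogat2, an enzyme of triglyceride synthesis, fell (-1.28 ± 0.189, adjusted p = 0.0178). Each of these lost the call without 3 of the 6 libraries in turn, for Zbp1 and Ccl12 the Pkd1-RC/RC ones. That count was 10, 11 and 9 without Pkd1-RC/RC replicate 1, 2 and 3, 22, 31 and 456 without digenic replicate 1, 2 and 3, and 7 with the sex pattern. Against Pkhd1-/-, 630 genes passed (479 up, 151 down; 1379 by DESeq2), with Sp110 (-3.34 ± 0.453, adjusted p = 0.00292) and March10, a ubiquitin ligase gene (-1.70 ± 0.244, adjusted p = 0.00400), among the falls. That count was 140 and 205 without Pkhd1-/- replicate 1 and 3, 331, 250 and 960 without digenic replicate 1, 2 and 3, and 4 with the sex pattern, where all Pkhd1-/- libraries were male and all digenic ones female. The interaction called 0 genes by edgeR with 1457 at an unadjusted p under 0.05 and 211 by DESeq2; it called 5 without wild-type replicate 2 and 196 without digenic replicate 3, which held adrenal transcripts. As lists, interferon response genes (median 1.80, adjusted p = 3.67e-35; adjusted p = 0.265) and macrophage genes (median 0.90, adjusted p = 7.55e-16; adjusted p = 0.280) rose in the interaction, with 16 and 14 members up adjusted over the list alone.

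At P12, 48 genes were called in Pkd1-RC/RC kidneys, against 3 and 8 at P0 and P3. The fit of all 36 libraries gave another order, 353, 14 and 37, for P0, P3 and P12. Rab6b, a vesicle-trafficking GTPase, fell from 43.7 to 14.5 CPM (-1.60 ± 0.173, adjusted p = 0.00147), Igfbp2, a binding protein of insulin-like growth factors, from 138 to 50.5 CPM (-1.45 ± 0.240, adjusted p = 0.0350), and Uroc1, a histidine-catabolic enzyme, by 1.43 ± 0.177 (adjusted p = 0.00312). Atp10d, annotated as a polymorphic pseudogene and so uncertain, rose from 5.89 to 20.6 CPM (1.80 ± 0.228, adjusted p = 0.00370) but fell in digenic kidneys (-0.82, adjusted p = 0.0234), and Nell2, a secreted glycoprotein gene, by 1.29 ± 0.164 (adjusted p = 0.00362). The rule for named genes also gave Vstm2a (-1.17 ± 0.207), Stbd1 (-1.11 ± 0.196) and Eno1b (1.43 ± 0.139, uncertain as a copy of Eno1). On chromosome 17 within 20 Mb of Pkd1 it gave Grm4 (2.63 ± 0.325), Prss22 (2.43 ± 0.315), Dynlt1b (2.28 ± 0.219, uncertain through near-identical copies), Tagap (0.996 ± 0.136), Igfals (-0.997 ± 0.156) and Rsph3a (-0.97 ± 0.104). Padi2 (1.29 ± 0.170) and Fbxo44 (-0.86 ± 0.104) lay in a stretch of chromosome 4 that held 9 of the 30 calls outside the Pkd1 window. Of these 9 genes, 5, 4 and 4 stayed called without wild-type replicate 1, 2 and 3, and 4, 5 and 5 without Pkd1-RC/RC replicate 1, 2 and 3. Principal cell genes rose (12 members, median 0.28, adjusted p = 3.99e-08; adjusted p = 0.280). Called members were 1 up over all genes, the sodium channel subunit Scnn1b (0.42 ± 0.0680, adjusted p = 0.0208), and 3 up adjusted over the list alone, with a median of 0.43 without wild-type replicate 2. Loop of Henle genes fell (14 members, median -0.21, adjusted p = 2.40e-07; adjusted p = 0.396). Member calls were 0 over all genes and 7 down adjusted over the list alone. The count was 48 of 18002 genes (21 up, 27 down; 163 by DESeq2), and 30, 30, 26 and 31 without wild-type replicate 1, 2 and 3 and Pkd1-RC/RC replicate 3; Igfbp2, Vstm2a, Stbd1, Igfals and Scnn1b lost the call when some of these libraries were left out.

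Pkhd1-/- kidneys at P12 differed from wild type in 6 genes (1 up, 5 down; 10 by DESeq2; 793 at an unadjusted p under 0.05). Adhfe1, an alcohol dehydrogenase gene on chromosome 1 (9547948 to 9580673), fell from 137 to 60.2 CPM (-1.19 ± 0.124, adjusted p = 0.00149). The others, chosen after their values were seen, were Pkhd1 and its antisense transcript, 2610203C22Rik (-1.09 ± 0.153), which overlaps Adhfe1, and the pseudogenes Gm5900 (-1.39 ± 0.144) and Gm10709 (1.10 ± 0.160), all uncertain except Pkhd1. The list of cystic disease genes (17 members, median -0.04) holds the deleted Pkhd1, the 1 member called over all genes, so its fall (adjusted p = 2.03e-06; adjusted p = 0.205) is fixed by the genotype. The mean change of the 16 other members was -0.05. Endothelium genes fell (median -0.22, adjusted p = 1.18e-07; adjusted p = 0.540) and cell cycle genes rose (median 0.23, adjusted p = 1.18e-07; adjusted p = 0.678). Called members were 0 for either list over all genes or adjusted over the list alone, and the cell cycle median was 0.08 and not called without wild-type replicate 3.

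**Figure D2:**
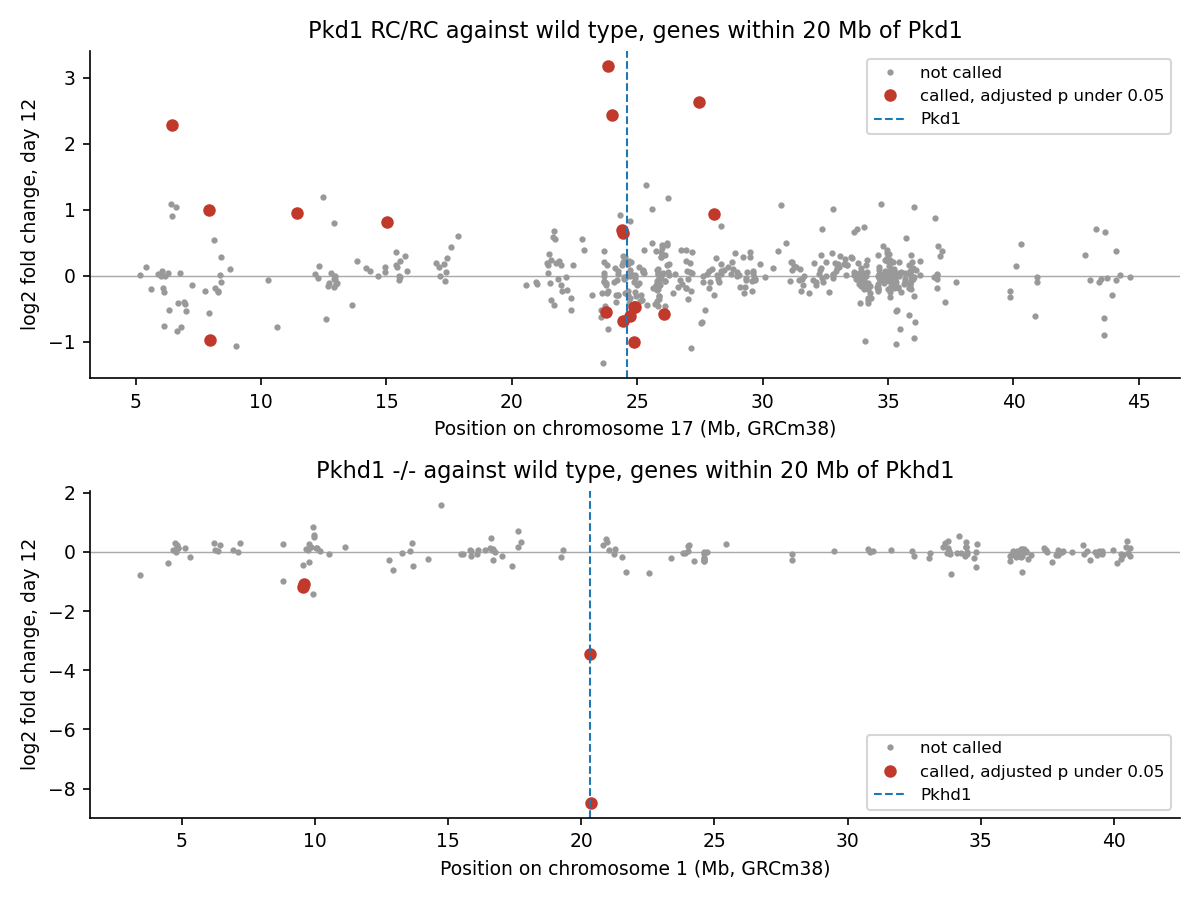
Log2 fold change at P12 of each tested gene against its position in Mb within 20 Mb of Pkd1 on chromosome 17 in Pkd1-RC/RC and of Pkhd1 on chromosome 1 in Pkhd1-/- kidneys, with called genes in red and a dashed line at the mutated gene. Grm4 lies 2.83 Mb and Dynlt1b 18.1 Mb from Pkd1, and Adhfe1 lies 10.5 Mb from Pkhd1.

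Genes called in the single mutants lay near the mutated gene more often than other tested genes. Of 49 genes called in Pkd1-RC/RC at any age, 18 (36.7%) lay within 20 Mb of Pkd1, against 2.97% of 18047 tested genes (odds ratio 19.6, Fisher's exact p = 1.20e-15, two-sided). All 18 were called at P12, where 11, 8 and 10 stayed called without wild-type replicate 1, 2 and 3, and 12, 10 and 10 without Pkd1-RC/RC replicate 1, 2 and 3. The odds ratio at P12 was then between 13.2 and 20.8. Of 6 genes besides Pkhd1 called in Pkhd1-/-, 4 (66.7%) lay within 20 Mb of Pkhd1, against 0.992% of tested genes (odds ratio 204, Fisher's exact p = 1.38e-07, two-sided). These 4 include the antisense transcript inside Pkhd1 and 2 genes that overlap each other. Without genes inside the mutated gene and with overlapping genes counted once, 2 of 4 lay near Pkhd1 (odds ratio 100.9, Fisher's exact p = 0.000579, two-sided) and 17 of 47 near Pkd1 (odds ratio 19.1, Fisher's exact p = 1.02e-14, two-sided). Signs were compared in a digenic comparison sharing no library, where 9 of 18 and 2 of 4 would agree without a shared effect. Against Pkhd1-/-, 17, 18 and 17 of the 18 genes near Pkd1 had the same sign in digenic kidneys at P0, P3 and P12. Against Pkd1-RC/RC, all 4 near Pkhd1 did at each age. Genes are not independent replicates in these tests.

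By P12, digenic kidneys had moved far from wild type. Slc5a2, the main glucose transporter of the early proximal tubule, fell from 410 ± 40.2 to 49.5 ± 18.4 CPM (-3.05 ± 0.276, adjusted p = 6.43e-05), while Pkd1-RC/RC held 260 ± 82.1 and Pkhd1-/- 452 ± 56.2 CPM. Egf, the growth factor made by the distal nephron, fell from 364 ± 137 to 38.4 ± 9.93 CPM (-3.24 ± 0.308, adjusted p = 0.000104). Sprr2f, a small proline-rich gene of injured epithelium, rose from 0.154 ± 0.1002 to 12.4 ± 4.86 CPM (6.36 ± 0.643, adjusted p = 0.000104), and its paralog Sprr2g by 4.96 ± 0.537 (adjusted p = 0.000123); both may share reads. The antigen-presentation genes Cd74 (48.7 ± 16.0 to 1589 ± 1193 CPM, 5.03 ± 0.738, adjusted p = 0.00187) and H2-Aa (16.9 ± 5.91 to 596 ± 456 CPM, 5.14 ± 0.784, adjusted p = 0.00234) rose, as did the complement gene C4b (5.73 ± 0.813, adjusted p = 0.00118) and the lymphoid chemokine gene Ccl21a (5.195 ± 0.673, adjusted p = 0.000891). H2-Aa and C4b lie within 20 Mb of Pkd1, C4b and Ccl21a have close paralogs, and Mir5107 (4.99) lies inside Cd74. Angptl7, a secreted angiopoietin-like factor, fell from 11.7 ± 3.14 to 0.857 ± 0.200 CPM (-3.76 ± 0.378, adjusted p = 0.000115) but stood at 39.3 ± 16.6 CPM in Pkd1-RC/RC. The other named genes were Asprv1 (5.40 ± 1.06), Klk1b5 (-3.55 ± 0.424, uncertain through paralogs), Snhg11 (-3.37 ± 0.721), Wfdc16 (-3.21 ± 0.541) and Aspg (-3.11 ± 0.361).

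**Figure D3:**
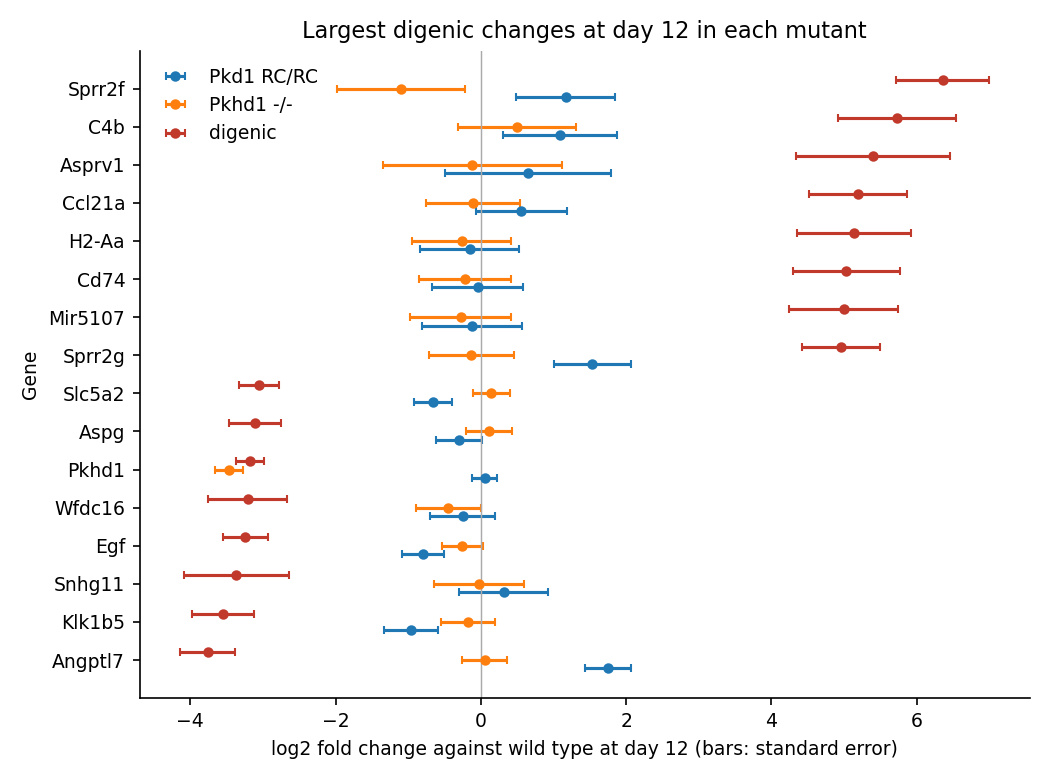
Log2 fold change against wild type ± SE at P12 in Pkd1-RC/RC, Pkhd1-/- and digenic kidneys (3 mice per group) for the named genes with the largest digenic changes. Digenic values run from -3.76 for Angptl7 to 6.36 for Sprr2f.

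Macrophage, neutrophil and tubular injury genes rose in digenic kidneys at P12. All 19 macrophage genes rose, both over all genes and adjusted over the list alone (median 2.31, adjusted p = 5.93e-26; adjusted p = 0.280), among them Cd14, the endotoxin co-receptor (2.005 ± 0.164, adjusted p = 1.45e-05), Cd68 (1.84 ± 0.193, adjusted p = 7.20e-05) and Cd163 (3.08 ± 0.330, adjusted p = 0.000104). All 8 neutrophil genes rose over all genes and adjusted over the list alone (median 4.03, adjusted p = 1.35e-06; adjusted p = 0.430), including Lcn2, which injured tubules also make (3.79 ± 0.475, adjusted p = 0.000760). Tubular injury genes rose (25 members, median 1.05, adjusted p = 2.54e-19; adjusted p = 0.205). Member calls were 20 up and 1 down over all genes and 21 up and 1 down adjusted over the list alone. Gdf15 (1.88 ± 0.144, adjusted p = 1.09e-05), the adhesion receptor Cd44 (1.23 ± 0.117, adjusted p = 4.30e-05) and the keratin Krt18 (1.52 ± 0.152, adjusted p = 6.37e-05) were among them. YAP targets rose (12 members, median 0.52, adjusted p = 0.000136; adjusted p = 0.396). Called members were 6 up over all genes and 7 up adjusted over the list alone, among them F3 (1.11 ± 0.119, adjusted p = 8.80e-05). Immediate early genes rose (11 members, median 0.84, adjusted p = 4.04e-05; adjusted p = 0.540). Member calls were 6 up over all genes and 7 up adjusted over the list alone. Interferon response genes rose (median 1.01, adjusted p = 0.00220; adjusted p = 0.751), with a median of only 0.29 without digenic replicate 1. Called members were 7 up and 1 down over all genes and 8 up and 1 down adjusted over the list alone. The matrix and fibrosis list had a median of only 0.09 (25 members, adjusted p = 0.0227; adjusted p = 0.807), yet 8 members rose by both counts, over all genes and adjusted over the list alone, such as the collagen crosslinker Lox (0.89 ± 0.0859, adjusted p = 4.36e-05) and smooth muscle actin Acta2 (0.90 ± 0.158, adjusted p = 0.00172). That median was 0.04 without wild-type replicate 3, 0.24 without digenic replicate 1, and -0.04 and not called without digenic replicate 2.

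Nephron segments moved in opposite directions at P12. Loop of Henle genes fell (14 members, median -0.73, adjusted p = 7.34e-15; adjusted p = 0.265). Member calls were 11 down over all genes and 12 down adjusted over the list alone, such as Umod, uromodulin (-0.78 ± 0.0869, adjusted p = 0.000108). Proximal tubule genes fell (30 members, median -0.71, adjusted p = 1.84e-11; adjusted p = 0.312). Called members were 15 down over all genes, and 2 up and 16 down adjusted over the list alone, such as the phosphate transporter Slc34a1 (-0.97 ± 0.114, adjusted p = 0.000142). Principal cell genes of the collecting duct rose (12 members, median 0.96, adjusted p = 6.03e-13; adjusted p = 0.205). Member calls were 9 up over all genes, and 9 up and 1 down adjusted over the list alone. Scnn1b (0.94 ± 0.0684, adjusted p = 8.54e-06) and the transcription factor Gata3 (0.86 ± 0.0969, adjusted p = 0.000115) were among them. The cAMP and vasopressin list rose (18 members, median 0.14, adjusted p = 0.0319; adjusted p = 0.540). Called members were 5 up and 1 down over all genes and 6 up and 1 down adjusted over the list alone, led by the phosphodiesterase Pde3b (1.58 ± 0.123, adjusted p = 1.09e-05) and the vasopressin receptor Avpr2 (1.21 ± 0.165, adjusted p = 0.000407). The list was not called without wild-type replicate 2 or digenic replicate 2, with a median of 0.13 in each case. Intercalated cell genes fell (14 members, median -0.23, adjusted p = 0.0168; adjusted p = 0.736). Member calls were 4 down over all genes, and 1 up and 5 down adjusted over the list alone, and the median was -0.13 and not called without digenic replicate 2. Endothelium genes fell (14 members, median -0.43, adjusted p = 1.67e-06; adjusted p = 0.586). Called members were 11 down over all genes and 12 down adjusted over the list alone, such as Emcn (-0.88 ± 0.132, adjusted p = 0.000693). Oxidative phosphorylation genes fell (22 members, median -0.32, adjusted p = 7.34e-06; adjusted p = 0.682). Member calls were 11 down over all genes and 17 down adjusted over the list alone.

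**Figure D4:**
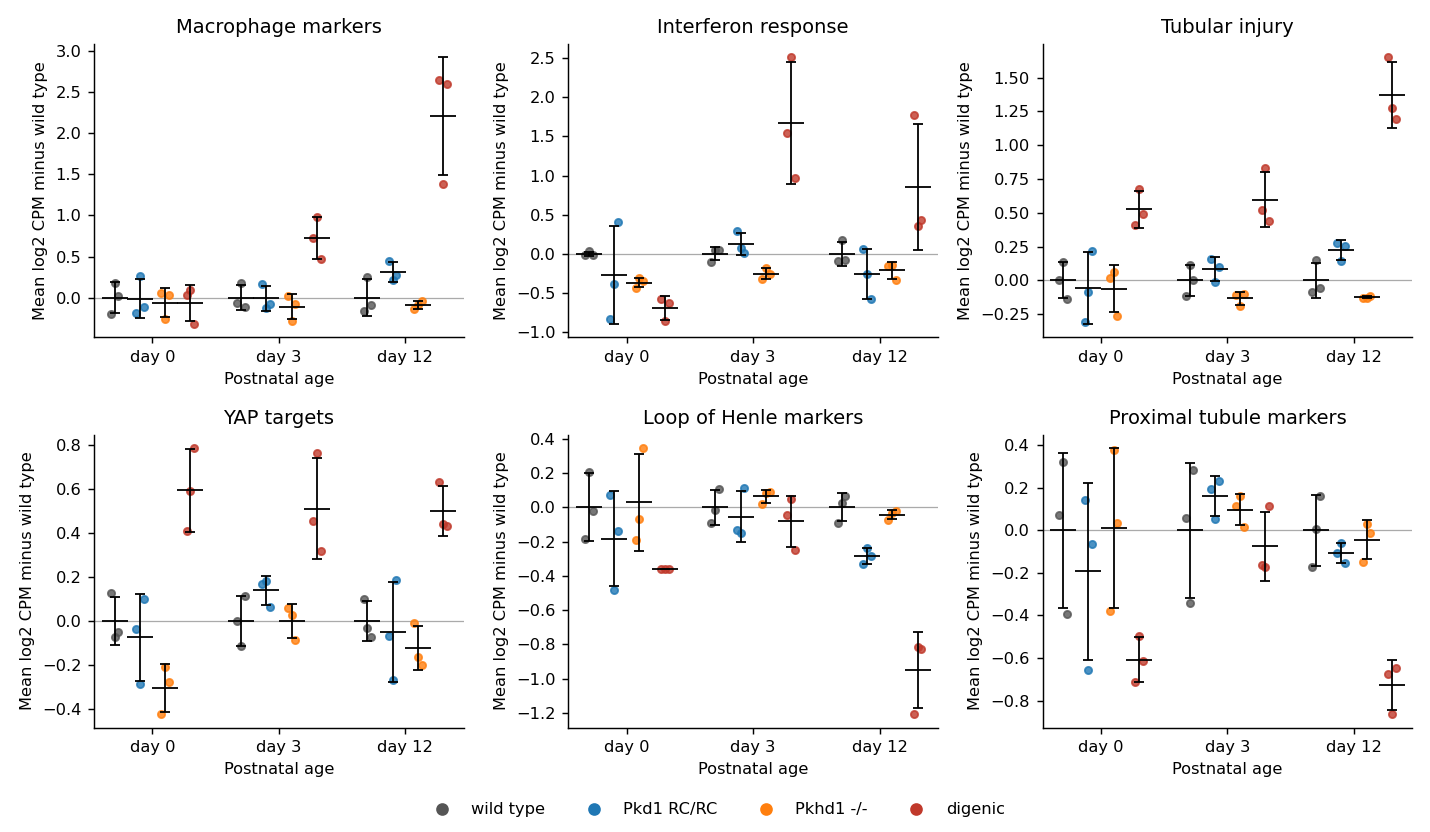
Mean log2 CPM of 6 gene lists in each library minus the wild-type mean of the age, by postnatal day and genotype, with bars for the mean and SD of 3 mice. The interferon response list in P3 digenic kidneys stands 0.97 to 2.51 above wild type, and the macrophage list stands highest in P12 digenic kidneys.

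In total, 4141 of 18002 genes passed between digenic and wild-type kidneys at P12 (2158 up, 1983 down; 1141 by at least 2-fold), and 2658 without wild-type replicate 3. Against Pkd1-RC/RC, 3512 genes passed (1848 up, 1664 down; 2205 without Pkd1-RC/RC replicate 1), led downward by Angptl7 (-5.51 ± 0.396, adjusted p = 5.04e-05) and upward by Serpina3f (6.98 ± 1.59), Tgtp2 (6.48 ± 1.55), Tgtp1 (6.39 ± 1.49) and the neutrophil granule gene Ngp (6.34 ± 1.23, adjusted p = 0.00708). Serpina3f, Tgtp1 and Tgtp2 lost that call when any 1 Pkd1-RC/RC replicate was left out. Against Pkhd1-/-, 5073 genes passed (2798 up, 2275 down), with Sprr2f at 7.46 ± 0.713 (adjusted p = 5.18e-05) and Angptl7 at -3.81 ± 0.379 (adjusted p = 7.41e-05). Without the libraries holding adrenal transcripts, 1 digenic library is left at P12, so that fit decides nothing.

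The interaction at P12 called 1542 genes (968 up, 574 down; 2729 by DESeq2), whose digenic change differed from the sum of both single changes. Angptl7 (-5.56 ± 0.495, adjusted p = 0.000683), Atp10d (-2.78 ± 0.325, adjusted p = 0.00172), Slc5a2 (-2.54 ± 0.367, adjusted p = 0.00568), Aspg (-2.92 ± 0.475, adjusted p = 0.00745) and Cpne4, a calcium-dependent membrane-binding protein gene (-2.90 ± 0.388, adjusted p = 0.00296), were lower than that sum. Sprr2f (6.29 ± 1.03, adjusted p = 0.00813), S100a8, a neutrophil calcium-binding protein gene (5.69 ± 1.08, adjusted p = 0.0158), and H2-Aa (5.55 ± 1.01, adjusted p = 0.0164; 5.52 and not called without Pkhd1-/- replicate 2) were higher. Serpina3f (8.43 ± 2.20), Ngp (6.76 ± 1.69), Fcgr4 (5.47 ± 1.29), S100a9 (5.40 ± 1.18), Snhg11 (-3.65 ± 0.943), Rgs11 (-3.44 ± 0.919, within 20 Mb of Pkd1) and Lgals4 (-3.04 ± 0.707) were called in 8 to 14 of 21 alternatives. Macrophage genes exceeded the sum (median 2.33, adjusted p = 2.56e-22; adjusted p = 0.280). Called members were 17 of 19 up over all genes and 17 up adjusted over the list alone. Tubular injury genes did so (median 0.99, adjusted p = 1.10e-17; adjusted p = 0.205). Member calls were 12 up over all genes, and 22 up and 1 down adjusted over the list alone, among them Gdf15 (2.13 ± 0.202, adjusted p = 0.000683). Matrix genes rose (median 0.50, adjusted p = 4.25e-09; adjusted p = 0.540). Called members were 10 up over all genes and 14 up adjusted over the list alone. Cilium genes fell (28 members, median -0.25, adjusted p = 0.00291; adjusted p = 0.646). Member calls were 4 down over all genes and 6 down adjusted over the list alone, among them Ift80 (-0.52 ± 0.126, adjusted p = 0.0270) and Cep290 (-0.91 ± 0.234, adjusted p = 0.0326), which were called in 13 and 11 of 21 alternatives. The count was 866 and 956 without wild-type replicate 2 and 3, 795 without Pkd1-RC/RC replicate 1, and 685, 558 and 723 without Pkhd1-/- replicate 1, 2 and 3.

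Changes with age set the scale for these differences. Between P0 and P12 in wild-type kidneys 8986 of 18049 genes passed in the fit of all 36 libraries (4721 up, 4265 down), 3091 of them by at least 2-fold. Six2, the transcription factor of nephron progenitors, fell from 45.0 to 0.182 CPM (-7.94 ± 0.403, adjusted p = 3.16e-14), and the fetal growth genes Igf2 (-5.55 ± 0.290, adjusted p = 3.60e-14) and H19 (-5.90 ± 0.338, adjusted p = 1.11e-13) fell, with Mir675 (-5.90) inside H19. Alb, the albumin gene of the liver, fell by 6.55 ± 1.54 (adjusted p = 0.00106), from a level that varied between P0 mice (48.6 ± 58.0 CPM). Egf rose from 7.25 to 368 CPM on the scale of all 36 libraries (5.67 ± 0.390, adjusted p = 8.75e-12), Kmo, an enzyme of tryptophan catabolism, by 7.21 ± 0.542 (adjusted p = 3.11e-11), Cyp4a14, a fatty acid hydroxylase, by 6.80 ± 0.896 (adjusted p = 1.10e-06), Folh1 by 6.33 ± 0.498 (adjusted p = 9.78e-11) and Dio1, the thyroid hormone deiodinase, by 6.01 ± 0.568 (adjusted p = 3.26e-09). Pkhd1 (1.56 ± 0.216, adjusted p = 1.01e-06), Pkd2 (1.41 ± 0.198, adjusted p = 1.33e-06) and Pkd1 (0.67 ± 0.154, adjusted p = 0.000687) rose over the same time.

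The effect of the digenic genotype changed between P0 and P12 for 1587 genes (943 up, 644 down; 2093 by DESeq2). That count was 2472 and 990 without P0 wild-type replicate 2 and 3, 891 without P0 digenic replicate 2, and 1019 and 1016 without P12 wild-type replicate 1 and 3. For the Pkd1-RC/RC effect 1 gene passed, Pik3c2g, a lipid kinase gene on chromosome 6 (139587221 to 139969284; -2.60 ± 0.435, adjusted p = 0.0293), chosen after its value was seen, with 1769 at an unadjusted p under 0.05 and 46 by DESeq2. That count was 3, 125 and 0 without P0 wild-type replicate 1, 2 and 3, and 0 and 67 without P0 Pkd1-RC/RC replicate 1 and 3. It was 0, 0 and 5 without P12 wild-type replicate 1, 2 and 3, and 22, 0 and 0 without P12 Pkd1-RC/RC replicate 1, 2 and 3. For the Pkhd1-/- effect 0 genes passed by edgeR, with 1229 at an unadjusted p under 0.05 and 0 by DESeq2; the count was 43 without P0 wild-type replicate 2, 1 without P0 Pkhd1-/- replicate 1 and 1 without P12 Pkhd1-/- replicate 3.

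Along the wild-type change from P0 to P12, digenic kidneys stood below the other genotypes at P12. A position was computed for each library over the 3091 genes with at least a 2-fold wild-type change, with 0 at the mean of P0 and 1 at the mean of P12 wild-type kidneys. At P12 the position was 1.0 ± 0.0408 (SD, n = 3) in wild type, 0.970 ± 0.0236 in Pkd1-RC/RC, 1.003 ± 0.0175 in Pkhd1-/- and 0.730 ± 0.0110 in digenic kidneys, whose range was 0.717 to 0.736. The digenic difference of -0.270 gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 mice allow, and 0.675 adjusted over 9 comparisons. At P0 the positions of Pkd1-RC/RC, Pkhd1-/- and digenic kidneys were 0.128 ± 0.0912, 0.0797 ± 0.0885 and 0.123 ± 0.0686, and at P3 all genotypes lay between 0.321 and 0.355.

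**Figure D5:**
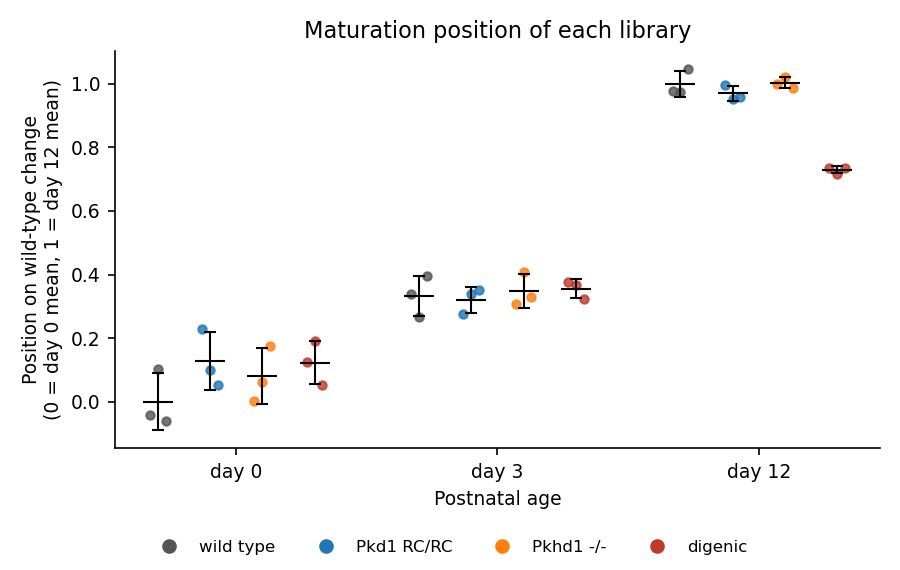
Position of each library along the wild-type change from P0 (0) to P12 (1) by postnatal day and genotype, with bars for the mean and SD of 3 mice. At P12 the digenic libraries lie between 0.717 and 0.736, below the other genotypes.

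Profiles of change were compared between the mutants at each age, across genes, which are not independent replicates. All mutants were set against the same 3 wild-type kidneys, which alone makes profiles correlate, so each correlation was compared with 20 simulated sets that share controls and nothing else. At P12 Pearson's r was 0.280 for Pkd1-RC/RC and digenic, 0.160 for Pkhd1-/- and digenic and 0.204 for both single mutants, against simulated means of 0.493, 0.492 and 0.496. In the same order it was 0.558, 0.420 and 0.565 at P0, against 0.508, 0.507 and 0.506, and 0.416, 0.221 and 0.488 at P3, against 0.511, 0.502 and 0.501. The covariance of Pkd1-RC/RC and digenic changes was above its simulated mean at each age, by 0.0488 at P0, 0.0243 at P3 and 0.0235 at P12. That of Pkhd1-/- and digenic changes differed from it by 0.0134, -0.00380 and -0.00235, and that of both single mutants by 0.0191, 0.00967 and -0.0138. The wild-type group of 3 cannot be divided into separate control sets of 2, so part of any excess may come from the shared controls. The simulated sets also hold no trend with gene length. Part of the P0 excess may come from that trend, whose P0 ranges are given above. Of 21 genes called up in Pkd1-RC/RC at P12, 17 were called up in digenic kidneys, and of 27 called down 13 were, against 2.52 and 2.97 expected for independent calls. Simulated sets that share controls and hold no true change had at most 1 called gene in common. Such sets call few genes in the first place, so this does not show how many shared calls the common controls add.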

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

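The tests of closeness to the mutated genes, with the ratio over genes called at P3, and of a lower share of tubule cells were chosen only after the result was seen, as were all regroupings of libraries and the fits with sex or gene length; the others were set before. Results stand here because a test of the difference between P0 and P12 found that the effect of a genotype changed with age. This was so for 1587 genes in digenic kidneys and 1 gene in Pkd1-RC/RC kidneys. Groups of 3 were not searched for single outlying libraries.

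Digenic effects that reversed or shrank with age, given as P12 minus P0 on the log2 scale ± SE, included Folh1 (-3.54 ± 0.591, adjusted p = 0.000324), Kmo (-3.66 ± 0.646, adjusted p = 0.000522) and Bst1 (-2.04 ± 0.382, adjusted p = 0.000966), which were high at P0. Those low at P0 were Haao (2.87 ± 0.543, adjusted p = 0.00105), Miox (2.31 ± 0.409, adjusted p = 0.000547), Kap (2.09 ± 0.502, adjusted p = 0.00895), Crisp1 (3.91 ± 1.11, adjusted p = 0.0262) and Prodh2 (2.20 ± 0.389, adjusted p = 0.000522). Effects that arose or grew by P12 included Sprr2f (5.95 ± 0.801, adjusted p = 3.37e-05), Sprr2g (2.99 ± 0.864, adjusted p = 0.0288), C4b (6.92 ± 1.67, adjusted p = 0.0101), Asprv1 (5.73 ± 0.871, adjusted p = 0.000116), Ccl21a (5.71 ± 0.615, adjusted p = 3.98e-06), H2-Aa (6.20 ± 1.01, adjusted p = 0.000324), Cd74 (5.76 ± 0.929, adjusted p = 0.000304) and Mir5107 inside Cd74 (5.47 ± 0.972, adjusted p = 0.000760). Falls that arose or grew were Klk1b5 (-2.66 ± 0.596, adjusted p = 0.00511), Egf (-2.48 ± 0.472, adjusted p = 0.00128), Aspg (-3.38 ± 0.530, adjusted p = 0.000138) and Slc5a2 (-2.20 ± 0.348, adjusted p = 0.000155).

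Among the genes that separated P12 digenic from wild-type kidneys, lower loop of Henle and proximal tubule genes stood beside higher macrophage and neutrophil genes. Gene length bias as the whole cause is argued against, since 4018 of the 4141 genes were called in the same direction with the length trend removed. A lower share of tubule cells that raises every other cell type alike is argued against too, since the endothelium median was -0.43 while the macrophage median was 2.31. This speaks only against that form. A changed mix of cell types in another form was not tested and stays open. Delayed maturation remains a candidate explanation for part of the change: of 2361 genes called in both, 2052 (86.9%) went against their P0 to P12 change in Pkhd1-/- kidneys, 893 of 1107 risen genes and 1159 of 1254 fallen ones. A delay of the whole program is not shown: nephron progenitor genes, which fell from P0 to P12 in wild type, were 0.269 below wild type (SD 0.385) and cell cycle genes 0.121 below (SD 0.165). Tissue damage by cysts, which the labels do not record, was not tested and stays open.

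The rise of interferon response genes in P3 digenic kidneys came in a group of 3 females. In the 9 groups with both sexes the list was -0.139 (female minus male, mean log2 CPM, SD 0.431), against a rise of 1.67, which argues against sex as its cause. With the length trend removed the median was 1.76, which argues against gene length. An infection in these litters or a response to the combined mutations may each be a source, and nothing in the data used here tests either.

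Genes called in the single mutants lay near the mutated gene, with odds ratios of 19.6 for Pkd1 and 204 for Pkhd1. A segment of another strain around each allele is a candidate explanation, and a segment would give such ratios. A response of the kidney to the mutation stays open. The digenic change of these 22 neighbours was about as large at P12 as at P0 (median ratio 1.13, interquartile range 0.942 to 1.40), but that bound assumed that responses grow with age. Over the 469 other genes called in P3 digenic kidneys the median ratio was 0.617 (interquartile range -0.862 to 2.19), so the ratio decides nothing. The 4118 other genes called at P12 did grow, from a median size of 0.268 at P0 to 0.606, but being chosen by their P12 change fixes that. An effect of the mutant allele itself on nearby genes stays open too.

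Other groupings of the same libraries were tested in the same way. With 3 against 3 libraries there are 10 splits, so the share of splits as large as the real one can never be under 0.1. At P0 the real count and the highest of the other splits were 3 and 1 for Pkd1-RC/RC, 2 and 2 for Pkhd1-/-, 121 and 0 for digenic, and 7 and 0 and 44 and 0 for digenic against Pkd1-RC/RC and Pkhd1-/-. At P3 these were 8 and 1, 3 and 5037, 487 and 1, 83 and 0, and 630 and 1, and at P12 48 and 112, 6 and 0, 4141 and 0, 3512 and 0, and 5073 and 11. For wild-type P12 against P0 they were 8986 and 5. The split with 5037 genes set wild-type replicates 1 and 3 and Pkhd1-/- replicate 2 of P3 against the rest, and points to a structure of the samples: in these libraries log2 levels correlated with gene length across genes by 0.110, 0.140 and 0.174, and in the rest by -0.206 to -0.254. The split with 112 genes held P12 wild-type replicates 1 and 2 and Pkd1-RC/RC replicate 1 on 1 side. For the interaction and the change of effect with age, genotype labels were drawn again within each age. This asks whether genotype had any effect, not whether effects add up or changed. In that sense chance could be excluded for the P12 interaction (1542 genes, 1 of 100 splits as large, highest other 1114). It could not be at P0 (1, 7 of 100, highest other 1933). For the change with age it could be in digenic kidneys (1587 genes, 3 of 70 splits as large, highest other 3177). It could not be in Pkd1-RC/RC (1, 22 of 70, highest other 129). With a real count of 0, all splits call as many, so nothing follows from the P3 interaction (100 of 100, highest other 29) or the change of the Pkhd1-/- effect (70 of 70, highest other 62). The split with 3177 exchanged all digenic and wild-type labels of P12 and none of P0, so that it added the 2 genotype effects in place of their difference.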

How the results depend on the processing

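The fits with sex, without adrenal libraries, without neighbouring genes and with the length trend removed were chosen after the data were seen. Over 752 results of named genes, alternatives kept direction and side of the threshold for 12012 values, lost the call for 732, gained it for 173 and reversed 0; over the 141 passing list tests they kept it for 1415 values, lost it for 369 and reversed 1. That was the adrenal list in P3 Pkd1-RC/RC, which fell without the libraries holding adrenal transcripts (adjusted p = 8.93e-05), as its construction requires. The cause was not tested for the other changes, except that fewer samples or genes were used where libraries or genes were left out. Depth limits the lowest genes: genes absent from the table were not analysed, and 1.5-fold changes were mostly missed at P0. Changes of count are given below where a count moved by over 1.5 times, for Pkd1-RC/RC, Pkhd1-/- and digenic against wild type, digenic against Pkd1-RC/RC and Pkhd1-/-, and the interaction.

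DESeq2 called 113, 9, 704, 64, 502 and 8 genes in these at P0, 65, 12, 1118, 525, 1379 and 211 at P3, 163 and 10 in the single mutants and 2729 in the interaction at P12, and 46 for the change of the Pkd1-RC/RC effect with age. With all 36 libraries in 1 fit the counts were 353, 18, 1645, 63, 1174 and 13 at P0, 14 for Pkd1-RC/RC and 194 for digenic against Pkd1-RC/RC at P3, and 3 for Pkhd1-/-, 2198 for digenic against Pkd1-RC/RC and 849 for the interaction at P12. With only the 2 groups compared they were 0 for Pkd1-RC/RC, 1 for Pkhd1-/- and 4 for digenic against Pkd1-RC/RC at P0, 59 for digenic against wild type and 37 against Pkd1-RC/RC at P3, and 2371 and 1449 for the same pair at P12. With the length trend removed they were 5 for Pkd1-RC/RC at P0 and 0 for the change of its effect with age.

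With the sex pattern of Xist and Ddx3y in the fit, digenic kidneys differed from wild type by 218 genes and from Pkhd1-/- by 79 at P0, and by 54, 7 and 4 genes from wild type, Pkd1-RC/RC and Pkhd1-/- at P3. With the sex of the column headers these were 221 against wild type and 2 for the interaction at P0, and 100, 4 and 131 at P3. Without the libraries holding adrenal transcripts the counts at P3 were 1 for Pkd1-RC/RC, 1 for Pkhd1-/-, 191 and 400 for digenic against Pkd1-RC/RC and Pkhd1-/- and 71 for the interaction; it was 2918 for digenic against Pkhd1-/- at P12 and 3 for the change of the Pkd1-RC/RC effect. Without genes within 20 Mb of Pkd1 and Pkhd1 the count was 0 for Pkhd1-/- at P0, 4 and 0 for Pkd1-RC/RC and Pkhd1-/- at P3, and 30 and 2 at P12. With an estimated correlation the number of passing list tests was 0. Over genes of at least 1 CPM the correlation of profiles was 0.165 for Pkhd1-/- and digenic at P3 and 0.0913 for both single mutants at P12.

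The numbers of replicates pair nothing in general, and a replicate block gave 0 genes for Pkd1-RC/RC, 1 for Pkhd1-/-, 56 for digenic and 25 for digenic against Pkhd1-/- at P0, 285, 27 and 393 for digenic against wild type, Pkd1-RC/RC and Pkhd1-/- at P3, and 0 for the change of the Pkd1-RC/RC effect with age.

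Leaving out 1 library at a time gave, for the 6 comparisons in the order above, 0 to 2, 1 to 3, 21 to 170, 2 to 8, 19 to 306 and 1 to 3 genes at P0. At P3 it gave 3 to 13, 2 to 4, 152 to 845, 9 to 456, 140 to 960 and 0 to 196, and at P12 26 to 44, 4 to 5, 2658 to 4410, 2205 to 3667, 3449 to 5009 and 558 to 2076. Changes of effect with age ran from 0 to 125 for Pkd1-RC/RC, 0 to 43 for Pkhd1-/- and 891 to 2472 for digenic kidneys, and the wild-type change from 7461 to 9151. Positions minus wild type ran, for digenic, Pkd1-RC/RC and Pkhd1-/-, from 0.0886 to 0.174, 0.0770 to 0.179 and 0.0316 to 0.131 at P0. They ran from -0.0104 to 0.0533, -0.0444 to 0.0193 and -0.0180 to 0.0457 at P3, and from -0.283 to -0.247, -0.0440 to -0.00695 and -0.00949 to 0.0262 at P12. Correlations of Pkd1-RC/RC and digenic, both single mutants, and Pkhd1-/- and digenic profiles ran from 0.570 to 0.678, 0.545 to 0.710 and 0.439 to 0.592 at P0. They ran from 0.477 to 0.574, 0.572 to 0.666 and 0.307 to 0.408 at P3, and from 0.310 to 0.376, 0.284 to 0.360 and 0.194 to 0.297 at P12. Fewer shared controls raise such correlations by themselves, and no expected value was simulated for 2 controls, so these ranges do not measure stability. Where a group kept 2 libraries, its spread was taken from the whole fit.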

Other observations

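The tests of the chromosome 4 stretch were chosen only after the result was seen. Further lists moved in single mutants and at the younger ages, each without a call over all genes unless given, and each losing its call with an estimated correlation, for which the second adjusted p is given. In P0 Pkd1-RC/RC kidneys cilium genes rose (median 0.32, adjusted p = 0.000455; adjusted p = 0.530) and oxidative phosphorylation (median -0.19, adjusted p = 1.18e-05; adjusted p = 0.653), glycolysis (median -0.32, adjusted p = 0.00469; adjusted p = 0.751), intercalated cell (median -0.34, adjusted p = 0.00704; adjusted p = 0.586) and neutrophil genes (median -0.53, adjusted p = 0.00469; adjusted p = 0.638) fell. With the gene length trend given in the report removed, the 5 medians were 0.28, -0.13, -0.34, -0.31 and -0.48. The glycolysis list was not called without wild-type replicate 2 (-0.24) or Pkd1-RC/RC replicate 1 (-0.13) and was -0.63 without Pkd1-RC/RC replicate 3. The intercalated cell list was not called without wild-type replicate 2 (-0.10) or Pkd1-RC/RC replicate 2 (-0.23), and the neutrophil median was -0.23 without Pkd1-RC/RC replicate 1. Adjusted over the list alone, 2 cilium genes were up, and 1 intercalated cell and 2 neutrophil genes were down. In P0 digenic kidneys Cdkn1c, the cell cycle inhibitor of mature podocytes, fell from 544 ± 32.2 to 342 ± 27.0 CPM (n = 3; -0.67 ± 0.134, adjusted p = 0.0442), a call lost when any 1 of the 6 libraries was left out. In P3 Pkhd1-/- kidneys ureteric tip genes fell (median -0.14, adjusted p = 0.00344; adjusted p = 0.280) and fatty acid oxidation genes rose (median 0.07, adjusted p = 0.0164; adjusted p = 0.788). Neither was called without wild-type replicate 2 (-0.14 and -0.02) or Pkhd1-/- replicate 2 (-0.11 and 0.01), and the latter was 0.15 without wild-type replicate 3. In P12 Pkd1-RC/RC kidneys distal convoluted tubule genes (median -0.24, adjusted p = 0.000505; adjusted p = 0.396) and stroma genes (median -0.13, adjusted p = 0.0437; adjusted p = 0.755) fell. The former median was -0.101 without wild-type replicate 2 and -0.105 without Pkd1-RC/RC replicate 1. Stroma was not called without wild-type replicate 1 or 3 or Pkd1-RC/RC replicate 1 (-0.12, -0.13 and -0.14). In P12 Pkhd1-/- kidneys immediate early genes fell (median -0.35, adjusted p = 0.000392; adjusted p = 0.594). That median was -0.23 without wild-type replicate 1, and -0.23 and -0.25 and not called without wild-type replicate 2 and Pkhd1-/- replicate 3. In the P0 interaction erythroid genes (median -0.90, adjusted p = 0.000803; adjusted p = 0.638) and muscle genes (median -0.85, adjusted p = 0.0232; adjusted p = 0.653) fell. Erythroid genes were not called without Pkhd1-/- replicate 1 (-0.31). Muscle genes were not called without replicate 2 of wild type, Pkd1-RC/RC, Pkhd1-/- or digenic (-0.78, -0.66, -0.29 and -0.725) or Pkhd1-/- replicate 1 (-0.73). In P3 digenic kidneys the liver-type gene Serpina1a fell (-0.76 ± 0.149, adjusted p = 0.0195; lost without wild-type replicate 3 or digenic replicate 1 or 2) within a gut, liver and pancreas list that fell (median -0.57, adjusted p = 0.0284; adjusted p = 0.679), and sex-linked genes fell (median -6.54, adjusted p = 0.0183; adjusted p = 0.540) in that group of females. The former list was not called without wild-type replicate 2 (-0.19) or digenic replicate 1 (-0.40), nor the latter without wild-type replicate 1 (-6.08) or digenic replicate 3 (-6.97). The lymphocyte, renin-angiotensin, unfolded protein response and Wnt target lists passed in no comparison, with smallest adjusted p-values of 0.0517, 0.193, 0.347 and 0.232.

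Transcripts of other tissues differed between libraries, here in CPM scaled by library total alone. Cyp11a1, an enzyme of steroid-making adrenal cells, exceeded 10 CPM in 8 libraries, at 12.1 to 71.3 CPM, and was at most 8.42 CPM in the others. These were P0 Pkd1-RC/RC replicate 2, P0 Pkhd1-/- replicate 1, P3 Pkd1-RC/RC replicate 1, P3 Pkhd1-/- replicate 1, P3 digenic replicate 3, P12 Pkhd1-/- replicate 3 and P12 digenic replicates 2 and 3. The adrenal list rose in P3 Pkd1-RC/RC (median 4.20, adjusted p = 0.0366; adjusted p = 0.807) and in P12 Pkhd1-/- (median 4.85, adjusted p = 0.00291; adjusted p = 0.679), and the fat list fell in P3 Pkd1-RC/RC (median -2.13, adjusted p = 0.000187; adjusted p = 0.631). The adrenal rise at P3 was not called without any 1 wild-type replicate (4.06, 4.58 and 4.06) or Pkd1-RC/RC replicate 1 (-0.70), nor that at P12 without Pkhd1-/- replicate 3 (0.01). The fat list was -0.98 and not called without wild-type replicate 2, the highest of the 6 libraries in this list, and -3.22 without Pkd1-RC/RC replicate 1. Alb reached 164 CPM, and Ucp1, a brown fat gene, reached 85.9 CPM at P12. Genes of ribosomal RNA type held 1.61% to 8.16% of counts, and the most abundant gene 1.0% to 5.13%.

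Levels of Xist and Ddx3y gave 3 females in P3 digenic, 3 males in P3 Pkhd1-/- and 3 males in P12 Pkd1-RC/RC groups, and both sexes in the 9 other groups. In 3 libraries this pattern differed from the sex in the column header, P3 Pkd1-RC/RC replicate 1, P3 Pkhd1-/- replicate 2 and P0 Pkhd1-/- replicate 1. Sp110 varied within groups, at 0.117, 2.01 and 2.93 CPM in the P12 digenic libraries.

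Of 30 genes called in P12 Pkd1-RC/RC kidneys outside the Pkd1 window, 9 lay on chromosome 4 between 140906344 and 148160482, where 82 genes were tested. Besides Padi2 and Fbxo44, these included, chosen after their values were seen, Arhgef19 (-0.60), and Znf41-ps (-1.81), Gm13251 (-1.17), Gm13139 (-1.46), Gm13152 (-1.34) and Gm13157 (-0.56), which belong to a family of zinc-finger copies that can share reads. In 10000 random draws of as many tested genes the fullest 10 Mb window held at most 6, a permutation p of 0.0001, the smallest these draws can give. The draws treat each gene as separate, while copies that share reads can be called together, so this p may overstate how far the calls gather. Of the 9 genes, 4 or 5 stayed called without any 1 of the 6 libraries. A chromosome segment of another strain carried by these mice may be the source, a hypothesis that the 9 genes in 1 window go with but do not decide. A response to the Pkd1 mutation stays open. The median size of the P12 digenic change of these genes was 0.169 of that in Pkd1-RC/RC, but they were chosen for their Pkd1-RC/RC change. At P0 the median sizes were 0.570 in Pkd1-RC/RC and 0.423 in digenic kidneys, and at P3 0.0603 and 0.408. Angptl7 lies close by, at 148495183 to 148500460, so a segment could bear on its interaction too.

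The authors' deposited table gives 70, 10 and 815 genes at an FDR under 0.05 for Pkd1-RC/RC, Pkhd1-/- and digenic kidneys at P0, 32, 13 and 499 at P3, and 179, 29 and 2802 at P12. Called in both that table and the tests here were 3, 2 and 121 genes at P0, 8, 3 and 388 at P3, and 48, 6 and 2705 at P12, all in the same direction. The correlation of log2 fold changes across genes was at least 0.9999 in the 9 comparisons.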
